A study of Mus musculus with 2 samples.

How the data were processed

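DNase-seq libraries from adrenal glands of 2 male B6CASTF1/J mice of 36 days were analysed, 1 library per animal. Per the labels the libraries are biological replicates 1 and 2 of the same tissue. Both carry the same donor label, and they were taken as separate animals because their descriptions give each male its own number and each sample its own identifier, so every statement on sharing between animals rests on that reading. All calls were made by the authors in each library separately on the mm10 build, per the deposited text files that describe them. The aligner, the peak and footprint callers, their versions and their thresholds are not given in the sources used here, and read-depth normalized signal tracks and alignments were not used here. How reads of the CAST parent mapped to the reference could not be tested, and neither could reads shared between near-identical genes.

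For each animal 2 deposited peak lists were used. The authors' height of each peak is a signal value whose scale the files do not state. Heights under 500 steps were whole multiples of 1 step, within 0.1 of a step, in 100% of cases in each list, with steps of 0.00749 in replicate 1 and 0.00642 in replicate 2. The larger list of each animal was the main one, with 182507 and 211528 peaks, and the smaller, with 120176 and 132016 peaks, an alternative. The deposited cut rate files give a false discovery rate q-value for stretches of bases, and all listed values are under 0.05. The lowest value within a peak was at most 0.0499 in the main lists of both animals and at most 0.000988 and 0.001 in the smaller lists. The deposited footprint files carry the same FDR value of 0.01 throughout, taken here as a threshold and not as a measurement.

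Peaks on the autosomes, X and Y were kept. Start sites and gene models came from the basic set of GENCODE release M21, with 77161 start sites and 21911 protein-coding genes, and sequence from GRCm38 patch p6, which is mm10. A peak was a promoter peak where its midpoint lay within 1000 bp of a start site and distal otherwise. Peaks were shared where at least 50% of their length was covered by peaks of the other animal. Chance overlap came from 100 circular shifts along each chromosome, and from 20 for regions and alternatives. The 21 gene lists with 231 genes, the 23 motif consensus sequences, the tests and their alternatives were fixed before the data were examined, and all 231 genes matched the annotation.

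Lists were tested by two-sided Fisher's exact tests on promoter peaks in both animals against other protein-coding genes, with exact 95% binomial intervals that cover counting error over genes only. A gene counted where each animal had a peak near any of its start sites, even where these were different peaks. Distal peaks found in both animals were given to the nearest protein-coding start site within 100 kb, and the mean per list was set against 10000 random lists of equal size matched in deciles of domain length, a two-sided permutation test whose smallest p is 0.0002. Motif shares in windows of 150 bp on distal peaks were set against windows 1000 bp to either side outside peaks, by two-sided Fisher's exact tests. By the same test, motif instances on footprints were set against instances of the reversed consensus, where both had at least 20 instances. Both were taken from the same set of distal peaks, not peak by peak. Benjamini-Hochberg adjustment ran over lists or motifs with a threshold of 0.05. Peaks, genes and motif instances are not independent replicates, so these p-values describe these 2 libraries.

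The genes named are a fixed panel of 31 genes, up to 3 members per list with the highest mean promoter height among those with promoter peaks in both animals, up to 4 members with none for cortex and medulla lists, and the 10 genes with the most distal peaks in both animals. Results for some of these genes and motifs are not reported. Fdx1 was named after its values were seen. Alternatives were promoter distances of 500 and 2500 bp, overlaps of 1 bp and 80%, the smaller lists, peaks above the median height, equal numbers of peaks, autosomes only, a peak in either animal, domains of 50 kb, no matching, genes with promoter peaks only, windows of 100 bp, GC-matched flanks, the reversed consensus, full containment in a footprint, and each animal left out. All GENCODE start sites, a comparison of promoter heights by list and alternatives for the promoter heights of panel genes were added after seeing the data.

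Peak overlap, promoter share, the list tests, the motif scan and the pairing of peaks were tested on simulated data, and the footprint comparisons and the weighting by GC content or height were not. Of the simulated peaks, 30.1% were planted on real ones and the others placed at random, and the overlap above chance came to 30.0%. Random lists with no change gave p under 0.05 in 4.50% of 200 cases for the distal test and 5.50% for the Fisher test, and lists with doubled distal counts did in 65% of cases. Planted NR5A sites were found in 100% of 2000 windows. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.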

Results

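Open chromatin was mapped by DNase-seq, in which the enzyme DNase I cuts accessible DNA, in adrenal glands of 2 male mice of 36 days. Both animals were of the strain B6CASTF1/J, hybrids of a classical laboratory strain and the wild-derived CAST strain. They formed 1 group of 2 biological replicates with no second condition, so each measurement is given for replicate 1 and then for replicate 2, and no difference between conditions could be tested. The adrenal gland joins a steroid-producing cortex to a medulla of chromaffin cells, which release catecholamines. Peak lists, called by the authors in each library by itself, held 182507 peaks in replicate 1 and 211528 in replicate 2, covering 33.5 and 36.1 Mb of the mm10 genome (1.23% and 1.32%). Median peak widths were 180 and 160 bp. Peak height is the authors' value for each peak, on a scale that the deposited texts do not state, and it is used here to describe and rank peaks within a list.

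The tallest open sites were shared by the 2 glands. Of the peaks in the highest of 4 equal classes by height, 97.2% in replicate 1 and 96.6% in replicate 2 were covered over at least 50% of their length by peaks of the other animal, and in the lowest class 42.4% and 28.3% were. Over all peaks the shares were 73.9% and 63.7%, against 1.37% and 1.29% after the other list was shifted along each chromosome, with highest values of 1.49% and 1.40% in 100 shifts. The 38384 peaks of replicate 1 with no overlap in replicate 2 had a median height of 0.367, and the 67134 such peaks of replicate 2 had one of 0.379, below the list medians of 0.719 and 0.751. Among 124919 peaks paired one to one, log2 heights correlated with a Pearson r of 0.908 and a Spearman rho of 0.881. That correlation is across peaks, which are not independent replicates, so no p-value goes with it. It was 0.945 over the 27359 pairs at promoters and 0.869 over the 97560 distal pairs.

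**Figure D1:**
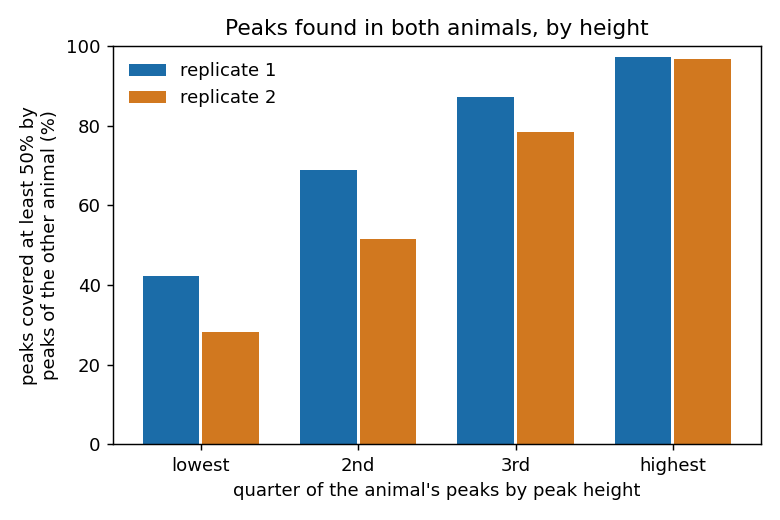
Share of each animal's peaks (y axis, %) covered over at least 50% of their length by peaks of the other animal, for 4 equal classes of that animal's peaks by height (x axis); bars give single values for replicate 1 and replicate 2. The share lies at 42.4% and 28.3% in the lowest class and at 97.2% and 96.6% in the highest.

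Promoters and exons held more peaks than shifted positions did, and intergenic sequence held fewer. In replicate 1, 20.9% of peaks had their midpoint within 1000 bp of an annotated start site, and in replicate 2 19.8% did, against 4.36% and 4.37% after 100 shifts, or 4.80 and 4.52 times as many. Exons away from promoters held 4.41% and 5.12% of peaks, 1.48 and 1.71 times the share after 20 shifts. Introns held 42.6% and 42.8%, and intergenic sequence held 32.1% and 32.3%, against 51.8% after shifting in both animals. Within each list promoter peaks were taller than intergenic ones, with median heights of 1.24 against 0.607 in replicate 1 and 1.91 against 0.584 in replicate 2. Shifted positions include sequence to which reads may not map, which is a limit on these ratios.

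The cholesterol supply genes, which bring the substrate of steroid synthesis into cortical cells, had accessible promoters throughout. All 15 members had a promoter peak in both animals, against 67.8% of the other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0222 over 21 lists). The tallest by the mean of both animals, whose heights differ in scale, stood at Npc1, a lysosomal cholesterol transporter, with heights of 14.1 in replicate 1 and 39.9 in replicate 2, at Dhcr7 (13.2 and 35.9) and at Hmgcs1 (11.5 and 26.5), both enzymes of cholesterol synthesis. Scarb1, the receptor that takes up cholesterol from lipoproteins, had 7.53 and 14.6. Genes are not independent replicates, and the call by Fisher's exact test was lost when promoters reached to 2500 bp (adjusted p = 0.0897) or when a peak in either animal sufficed (0.0853), within a range of 0.00563 to 0.0897 over the alternatives.

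Steroid synthesis genes were mostly accessible, with promoter peaks in both animals for 12 of 14 members. This share of 85.7% did not differ from that of other genes by the same exact test (adjusted p = 0.351). Por, which passes electrons to microsomal P450 enzymes, had promoter heights of 14.3 and 31.4, Fdxr, which does so in mitochondria, 11.6 and 26.6, and Stard4, a cholesterol carrier, 8.35 and 19.5. Star, which moves cholesterol into mitochondria, had 4.40 and 4.55, and Cyp11a1, which makes pregnenolone there, had 4.31 and 5.79. The Star value belongs to the start that the basic set keeps. A peak further upstream, over a start that only the full annotation holds, was counted as distal here and had 5.21 and 8.91. Akr1b7 had 3.27 and 4.64, Cyp21a1 had 3.20 and 2.34 and Cyp11b1 had 1.73 and 2.64. Cyp11b2, the aldosterone synthase gene, had a peak of 0.92 in replicate 1 and none in replicate 2, and Hsd3b1 had none in either animal. Inside Hsd3b1, 1513 bp from its start and so counted as distal, a peak of 2.04 and 1.55 was found in both animals. Cyp11b1 and Cyp11b2, Cyp21a1 and its pseudogene, and the Hsd3b family are near-identical copies whose reads can be shared, so their values are uncertain.

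Regulators of the cortex and of its response to ACTH were accessible too, without passing the test as lists. Promoter peaks in both animals were found for 11 of 12 cortical identity factors (adjusted p = 0.178) and 14 of 15 genes of ACTH and angiotensin signalling (0.113 by the exact test, or 0.0478 from replicate 2 alone). Nr5a1, the master regulator of steroid-producing cells, had promoter heights of 3.89 in replicate 1 and 10.1 in replicate 2, in a peak at position 38714441 to 38714640 of chromosome 2 in replicate 1. Nr4a1 had 10.7 and 30.1 and Cited2 had 9.52 and 15.5. Nr0b1, which restrains Nr5a1, had no promoter peak in replicate 1 and one of 0.44 in replicate 2. In the ACTH pathway Prkaca had 9.67 and 27.3, Crem had 9.02 and 19.6 and Creb1 had 8.96 and 22.5, while the ACTH receptor gene Mc2r had 1.24 and 0.73 and its partner Mrap had 5.90 and 8.64.

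All 10 genes of the capsule and of Wnt or hedgehog zonation had promoter peaks in both animals (adjusted p = 0.0960 by the exact test, within a range of 0.0361 in the smaller peak lists to 0.167 within 2500 bp). Znrf3, which restrains Wnt signalling, had heights of 8.73 and 19.04, Axin2 had 5.75 and 15.6, Wnt4 had 3.32 and 12.4, Gli1 had 3.54 and 7.54 and Shh had 0.80 and 1.17. All 4 genes of the X-zone, the fetal remnant of the mouse cortex, had one as well (0.386): Thrb with 3.86 and 13.1, Cyp17a1 with 1.41 and 1.03, Pik3c2g with 0.65 and 0.73, and the marker Akr1c18 with 0.34 and 0.30. For Shh and for Pik3c2g the peaks counted did not overlap between the animals.

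In the medulla list, 18 of 21 genes had promoter peaks in both animals (adjusted p = 0.177 by the exact test). The vesicular transporter gene Slc18a1 had heights of 8.004 and 31.2, and the granule proteins Chgb, Chga and Scg2 had 6.19 and 14.03, 3.35 and 5.32, and 3.14 and 6.01. The catecholamine enzymes stood lower: Th had 0.67 and 0.76, Dbh had 1.08 and 0.65, and Ddc and Pnmt had no promoter peak in either animal. The transcription factor gene Hand2 had 0.74 and 0.86.

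Among genes of supporting cells, the exact test was run on promoter peaks in both animals for 11 of 12 endothelial genes (adjusted p = 0.178), 9 of 12 stromal and smooth muscle genes (0.843), 8 of 12 macrophage and leukocyte genes (1), 8 of 8 adipocyte genes (0.128) and 4 of 8 sustentacular and Schwann genes (0.368). None of these lists passed its threshold against the 67.8% of other genes, so these counts alone do not show the presence of these cells. Macrophage and leukocyte genes passed it, below other genes, in the smaller peak lists (25% of members, exact test, adjusted p = 0.0277) and among peaks above the median height (25%, 0.0407). Kdr stood at 2.67 and 6.17, Flt1 at 2.04 and 5.81, Eng at 1.80 and 4.42 and Cdh5 at 0.99 and 2.14. Pdgfra stood at 4.77 and 10.6, Col1a1 at 6.10 and 7.51, Cidea at 2.10 and 4.24, Pparg at 2.70 and 2.80 and Cd68 at 1.37 and 2.07. The Pparg values belong to different start sites on chromosome 6. Their peaks lay at 115421061 to 115421240 in replicate 1 and at 115360921 to 115361200 in replicate 2. Sox10 and Csf1r had no promoter peak in either animal.

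Genes of several other cell types had few promoter peaks found in both animals. Promoter peaks in both animals were found for 1 of 10 genes of T and B cells (Lck, adjusted p = 0.00554), 1 of 8 keratinocyte genes (Krt10, 0.0186), 2 of 10 hepatocyte genes (Cyp2e1 and Cyp3a11, 0.0186), 1 of 7 erythroid genes (0.0237) and 3 of 10 kidney tubule genes (Aqp2, Pax2 and Lrp2, 0.0482), each below other genes by the exact test. The gonadal list with 6 of 11 (0.406), the muscle list with 4 of 10 (0.164) and the neuron list with 7 of 10 (1) did not pass, though muscle genes did in the smaller lists (20%, 0.0188) and above the median height (20%, 0.0407), by the same exact test. For Lrp2 the peaks counted did not overlap between the animals. Alb had a peak of 0.26 in replicate 1 alone and Myod1 one of 0.26 in replicate 2 alone. All 12 housekeeping genes had one (0.0432), among them Rplp0 at 13.9 and 25.3, Actb at 9.76 and 27.4 and Ywhaz at 11.4 and 23.4. Without replicate 1 the calls for T and B cells (40% of members, adjusted p = 0.0829), kidney tubule (40%, 0.0829) and hepatocytes (70%, 1) were lost in the exact test, and the housekeeping call was lost without either animal (0.0749 and 0.0706). Within 2500 bp the exact test no longer called the erythroid (adjusted p = 0.0897), keratinocyte (0.113), hepatocyte (0.249), kidney tubule (0.100) and housekeeping (0.0897) lists. With a peak in either animal the exact test no longer called T and B cells (40%, adjusted p = 0.105), kidney tubule (40%, 0.105), hepatocytes (80%, 0.775) and housekeeping (0.105). Of the 21 lists, 9 had an unadjusted p under 0.05 and 7 an adjusted one.

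**Figure D2:**
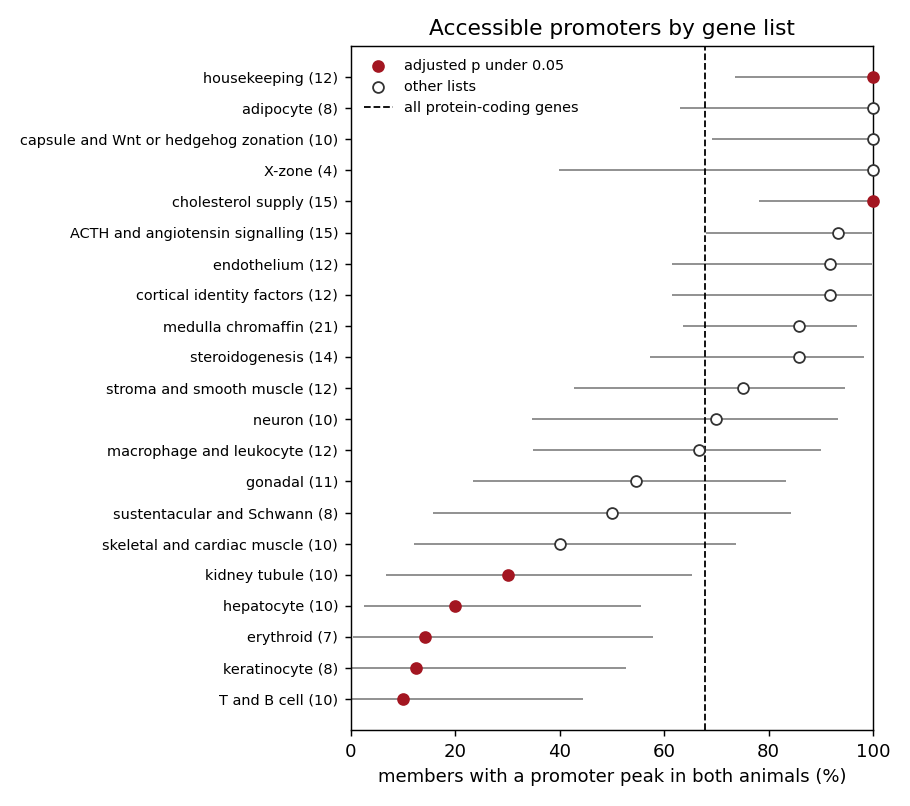
Share of list members with a promoter peak in both animals (x axis, %) for 21 gene lists (y axis, number of members in brackets); points give the share, lines its exact 95% binomial interval over genes, filled points an adjusted p under 0.05 and the dashed line all protein-coding genes at 67.8%. Cholesterol supply and housekeeping lie at 100%, and T and B cell genes at 10%.

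Steroid synthesis genes had a mean of 7.64 distal peaks found in both animals, against 3.76 ± 1.07 (SD) in 10000 random lists matched on domain length, and cortical identity factors had 12.2 against 7.02 ± 1.90. Neither difference passed the two-sided permutation test after adjustment over 21 lists (p = 0.0040 and 0.0218, adjusted p = 0.0651 and 0.146), and housekeeping genes stood as far out, with 6.25 against 2.59 ± 0.975 (0.00620, adjusted p = 0.0651). No list passed this test and 5 had an unadjusted p under 0.05, the others being cholesterol supply (6.27 against 3.95, 0.0278) and endothelium (9.58 against 5.78, 0.0456). The medulla list had a mean of 4.57 against 5.98 (0.246). With the peaks of 1 animal alone, steroid synthesis genes passed the permutation test in each: the mean was 12.6 without replicate 1 (adjusted p = 0.0273) and 15.9 without replicate 2 (0.0042), with a range of 0.0042 to 0.107 over the alternatives. Cortical identity factors passed too, at 21.8 (0.0273) and 18.3 (0.0280), with a range of 0.0042 to 0.186. Single genes weighed on these means. Of the distal peaks near steroid synthesis genes, Fdx1 held 61 of 223 in replicate 1 and 21 of 176 in replicate 2. Of the 223, 107 were shared. Near cortical identity factors Zbtb20, with a domain of 579 kb, held 59 of 220 and 68 of 261. The tests of these means were not repeated without Fdx1 or Zbtb20.

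Scarb1 had 52 distal peaks in replicate 1 and 38 in replicate 2, with 25 of the former shared. Fdx1, which carries electrons to mitochondrial P450 enzymes, had 61 and 21 with 12 shared, Cyp11a1 had 34 and 21 with 12 shared, and Star had 17 and 9 with 7 shared. The tallest distal peak paired one to one near Cyp11a1 lay at position 58009041 to 58009340 of chromosome 9, with heights of 5.92 and 7.65, inside an intron in the full annotation. Near Star it lay at 25806181 to 25806580 of chromosome 8, with 5.21 and 8.91. The Star site spans the outermost start of the gene in the full annotation, at 25806555. The basic set used here leaves out that start, and the site lay at -2093 bp from the nearest start it keeps. The Star site therefore counts as distal only under the basic set. Across the genome, 82604 shared distal peaks fell to a gene, a mean of 3.77 and a median of 2 per gene. By counts in each animal, shared or not, the most stood near Pde4d, a phosphodiesterase that breaks down cyclic AMP (79 and 82), Tns1 (74 and 101), Zfhx3 (89 and 72), Foxp1 (66 and 84), Kcnma1 (64 and 80), Zbtb20 (59 and 68), Lpp (62 and 58), Kalrn (58 and 57) and Dlc1 (56 and 56). Shared counts were 55 for Pde4d, 63 for Tns1 and 51 for Zfhx3. This ranking is not matched on domain length, which ran from 296 kb (Tns1) to 1268 kb (Pde4d) among the genes named. For Scarb1 the domain length was 105 kb.

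Distal peaks were rich in motifs of insulator, AP-1, cyclic AMP and nuclear receptor factors. Windows of 150 bp on distal peaks were compared with windows 1000 bp to either side by two-sided Fisher's exact tests over 23 motifs, and 18 motifs stood higher and 3 lower in both animals. The CTCF motif was in 4.34% and 3.80% of peaks, a log2 ratio over flanks of 6.70 ± 0.14 (SE) in replicate 1 and 6.50 ± 0.13 in replicate 2. AP-1 was in 15.5% and 12.1% of peaks (log2 ratios 2.68 and 2.35), the CRE of cyclic AMP signalling in 0.515% and 0.329% (2.71 and 1.89), and the glucocorticoid and androgen response element in 0.465% and 0.318% (2.29 and 1.71). The motif of NR5A factors, to which Nr5a1 belongs, was in 3.54% and 3.20% of peaks against 1.13% of flanks in both animals (1.65 and 1.5), and that of NR4A factors had 1.40 and 1.20. REST, the repressor of neuronal genes, had 7.68 and 7.87 over only 2 flanking windows with the motif, and NFI had 5.42 and 5.19.

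The motif of HNF1 stood lower in peaks than in flanks, by log2 ratios of -3.12 and -1.40, over only 2 and 8 peak windows with the motif. MEF2 and HNF4, listed with HNF1 as factors of other organs, stood higher, with 0.77 and 0.27 and with 0.47 and 0.59. The GATA motif stood slightly lower, with -0.09 and -0.37. By the exact test DR1 did not differ in replicate 1 (adjusted p = 0.511) nor RUNX in replicate 2 (0.0993). These directions depend on the comparison: against flanks matched on GC content no motif stood lower and GATA stood higher (0.45), and against the reversed consensus CRE had -0.50 and ETS -2.14. Reversal removes the CG pair of the CRE and ETS motifs, so both forms need not be equally common. Their negative ratios therefore do not bear on enrichment over flanks. Motif content moved with height: CTCF was in 0.944% and 0.761% of distal peaks in the lowest of 10 height classes and in 17.1% and 16.0% in the highest, and NR5A in 2.94% and 2.32% in the lowest, 3.95% and 4.10% in the fifth and 1.84% and 1.58% in the highest.

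Footprints, short stretches protected from DNase I within open chromatin, lay on many of these motifs. CTCF motifs in distal peaks lay on a footprint in 89.0% and 89.6% of instances, REST motifs in 81.7% and 85.3% and NFI motifs in 65.6% and 66.0%, with too few instances of the reversed consensus for a test. CRE motifs did so in 64.5% and 55.2% against 14.97% and 14.2% of the reversed consensus, NR5A motifs in 32.7% and 34.2% against 17.6% and 14.9%, and AP-1 motifs in 32.6% and 24.4% against 16.6% and 14.3%. Of 18 motifs with a test, 12 lay on footprints more often than their reversed consensus in both animals and 0 less often, by two-sided Fisher's exact test with adjustment. The glucocorticoid and androgen response element passed in replicate 1 (15.3% against 3.57%, exact test, adjusted p = 0.000572) but not in replicate 2 (9.61% against 7.81%, 0.690). GATA motifs did not pass the exact test, with 6.76% and 5.11% against 6.62% and 5.24% (adjusted p = 0.699 and 0.715). The authors' lists held 345606 and 395540 footprints of median width 10 bp. Within peaks, 47.1% and 37.4% of them overlapped a footprint of the other animal by at least 50%, against 20.97% and 16.0% after shifts within the peaks. DNase I has sequence preferences of its own, which the reversed consensus does not remove. Both forms were scanned in the same set of distal peaks but could lie in different peaks. Peak height was not matched between them. Footprints were found in 40.8% and 35.8% of peaks in the lowest of 4 height classes and in 97.2% and 95.5% in the highest. The CRE was in 0.291% and 0.132% of distal peaks in the lowest of 10 height classes and in 1.05% and 0.577% in the highest. NR5A was rarer in the highest class, and the effect on these shares was not tested.

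The NR5A consensus was looked for at 14 cortex genes, in 11 promoter regions and 84 distal peaks paired one to one. It occurred 6 times, never in a promoter peak, and 3 of the 6 lay on a footprint over at least 50% of their length in both animals. In windows of 150 bp it was in 1.09% and 1.05% of all promoter peaks, so its absence from 11 promoter regions carries little weight. Among all distal peaks it was in 3.54% and 3.20%, and the 6 were not tested against these shares. At Cyp11a1, TCAAGGCCA stood at position 58009145 to 58009153 of chromosome 9 in the distal peak described above, with 100% of its length on a footprint in both animals. Scarb1 had TCAAGGCCA at 125286391 to 125286399 and TCAAGGTCA at 125325449 to 125325457 of chromosome 5, both in introns, with 88.9% and 100% and with 100% and 77.8% on a footprint. Of the other instances, that near Akr1b7 had 100% and 22.2% of its length on a footprint, another near Scarb1 had 0% and 100%, and that near Mrap had none in either animal.

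The sex chromosomes held few called peaks per Mb of the assembly. The X held 28.5 and 33.9 peaks per Mb against 72.1 and 83.5 on autosomes, ratios of 0.396 and 0.405, and the autosome with the fewest held 58.7 and 67.4. Median heights on the X were 0.434 and 0.398, against 0.726 and 0.764 on autosomes. The Y held 96 and 130 peaks. Sequence to which reads may not map was not taken out of these lengths, so low densities need not mean little open chromatin. Both animals are male per the labels, with a single X. Among taller peaks the X ratio was lower, at 0.237 and 0.246 for peaks above the median height of each list.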

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

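The test of peak edges was chosen only after the result was seen. A signal lay in the cut rate files, which none of the comparisons above use: bases under the FDR threshold of 0.05 lay outside peaks over 19.5 Mb in replicate 1 and 24.8 Mb in replicate 2, and 63496 and 57363 stretches held no peak at all. In both animals at least 96.9% of the outside bases lay in stretches that also hold a peak, so the edges of called peaks are a candidate explanation for nearly all of that length. The stretches with no peak were short, with median widths of 5 and 6 bp. Chance calls alone were argued against, since 18.3% and 12.97% of these stretches overlapped a peak of the other animal, against at most 1.59% and 1.53% in 20 shifted sets, at least 8.46 times as often. What else sets them apart stays open, and no biological explanation was tested because the design has 1 group.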

How the results depend on the processing

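Of 773 alternative values, 645 were marked as unchanged. For lists and motifs that meant the same direction and side of the threshold, and for counts a change of at most 1.5 times. Overlaps and promoter shares had to exceed the shifted sets, and the height correlation to stay within its interval. Other values had to move within the spread between the animals. Part was fixed in advance: with 1 animal left out, panel heights cannot leave that spread and motifs called in both animals stay called. Peak counts depend on the list by construction: the smaller lists held 120176 and 132016 peaks, and peaks above the median height numbered 91873 and 106183. The height correlation was 0.906 with peaks shared by 1 bp and 0.904 in the smaller lists. Promoter lists above other genes, 2 in the main setting, were 3 within 500 bp, 3 in the smaller lists, 0 within 2500 bp, 0 with a peak in either animal, 1 with all GENCODE start sites (chosen after seeing the data) and 1 to 2 with 1 animal left out. Lists below, 5 in the main setting, were 7 in the smaller lists, 7 above the median height, 1 within 2500 bp, 2 with a peak in either animal and 2 to 5 with 1 animal left out. Distal lists above, 0 in the main setting, were 2 within 50 kb, 3 without matching, 2 with peaks above the median height and 2 to 3 with 1 animal left out. Over all footprints of replicate 2, inside peaks or not, the shared part rose from 36.7% to 44.8% at 1 bp, which is a weaker demand. The X ratio was 0.368 and 0.344 in the smaller lists and 0.237 and 0.246 above the median height, and the Y ratio 0.00596 and 0.00687 and then 0.00356 and 0.0036. Motifs below their flanks, 3 in the main setting, were 0 with GC-matched flanks. Directions reversed in 38 cases. For promoter lists with a peak above the median height these were the X-zone (50%), medulla (57.1%), stroma (33.3%) and neuron (50%); in the smaller lists stroma (50%) and neuron (60%); neuron also at 500 bp (60%) and 2500 bp (70%); with a peak in either animal macrophage (83.3%), hepatocyte (80%) and gonadal (72.7%); with all start sites macrophage (75%); and with 1 animal left out macrophage (75% in both) and gonadal (54.5% to 72.7%). For distal lists they were, without matching, medulla (4.57), Schwann (4.38), T and B cell (2.20), kidney (4), neuron (5.10) and gonadal (5.09); within 50 kb Schwann (4.13) and muscle (3.40); among genes with a promoter peak Schwann (6.50) and muscle (5.25); above the median height T and B cell (0.70) and muscle (1.70); and with 1 animal left out T and B cell (2.40 to 3.60), muscle (4.60 to 6.40) and keratinocyte (2.5 to 4). None of these list values passed a threshold in either setting except the hepatocyte list, which had in the main one. For motifs in peaks the log2 ratios were, against the reversed consensus, CRE -0.50, GATA 0.60, ETS -2.14 and HNF1 1.01, for GATA 0.45 with GC-matched flanks and for DR1 -0.13 above the median height. Those of CRE and ETS compare forms with and without a CG pair and do not bear on enrichment over flanks. For motifs on footprints the differences in percentage points were PU1 -0.259 with full containment, and with 1 animal left out GATA -0.135 to 0.139. Apart from settings that change by construction, the cause was not tested. A stricter set of footprints was not run for either footprint result, because the files carry 1 constant value. No paired analysis was possible because the design has a single group. Read depth, which is not stated, limits how low a peak can be called.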

Other observations

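The comparison of promoter heights by list, the comparison of sharing by list and its repeat without Fdx1, the test of low peak height and the GC-weighted comparison of motifs were chosen only after results were seen. Among genes with a promoter peak in both animals, promoters of cholesterol supply genes were the tallest, with a mean log2 height of 3.77 against 2.40 ± 0.39 (SD) in random lists of equal size (two-sided permutation test, p = 0.0002, the smallest these permutations can give, adjusted p = 0.00113 over 17 lists), and housekeeping genes had 3.60 (adjusted p = 0.00291). Steroid synthesis genes had 2.66 (0.626), cortical identity factors 1.78 (0.233), ACTH and angiotensin genes 2.25 (0.668), capsule and zonation genes 2.06 (0.536) and Schwann genes 1.70 (0.420), none different from random lists. Several lists of the gland had lower promoters: the medulla list stood at 0.76 (0.00113), macrophages at -0.51 (0.00113), endothelium at 0.54 (0.00136), stroma at 0.40 (0.00136), adipocytes at 0.50 (0.00382) and the X-zone at 0.23 (0.0192). So did kidney tubule at -0.82 (0.00291), muscle at 0.08 (0.0155), neurons at 0.78 (0.0163) and gonads at 0.74 (0.0263). With each animal by itself, 2 lists stood higher and 10 lower, as with both. The random lists were not matched on GC content, and the share of each cell type in the gland was not measured. Lower heights in the whole gland therefore do not show how open these promoters are in their own cells.

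Distal peaks of replicate 1 near steroid synthesis genes were shared with replicate 2 less often than others: 107 of 223, or 48.0%, against 72.3% of all distal peaks of replicate 1 (permutation test with random lists matched on their number of distal peaks, p = 0.0002, the smallest possible, adjusted p = 0.0084 over 42 tests). Fdx1, with 12 of 61 shared, held much of this difference, and without it the share was 58.6%, against 72.3% (unadjusted permutation p = 0.0010), 73.1% expected from GC content (0.0018) and 84.0% expected from height (0.0002, the smallest possible). GC content was argued against as the whole cause in replicate 1, since 69.6% of these peaks would be shared from it (adjusted p = 0.0084 by permutation), and low height because the peaks were not low, with a median of 0.854 against 0.651 for all distal peaks, from which 81.4% would be shared. In replicate 2 the share was 64.8% against 61.5% of all distal peaks (adjusted p = 0.930 by permutation), and it passed neither against the 60.6% expected from GC content (0.958) nor against the 78.1% from height (0.153), but did against the 78.6% from both together (0.0336), so whether replicate 2 shows the pattern depends on the correction. Other lists depended on it as well: in replicate 1 cholesterol supply genes had 61.4% (0.368 uncorrected, 0.0644 with GC content, 0.0462 with height and 0.0084 with both, by permutation) and keratinocyte genes 46.9% (0.0672, 0.0210, 0.858 and 0.862), and neither passed with any of the 4 in replicate 2. Whether uncalled accessible stretches are involved stays open, because the 0.98% of unshared peaks near steroid synthesis genes, and 4.21% of all unshared distal peaks, that lay on bases under the FDR threshold in replicate 2 are limited by the small width of stretches with no peak, and cell content, dissection and mapping of CAST reads were not tested.

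Motif shares in distal peaks found in 1 animal alone are given with no test, for motifs chosen after the values were seen. Those of replicate 1 alone had AP-1 in 14.97%, near the 15.7% of shared peaks, and those of replicate 2 alone in 6.81%, or 7.74% when weighted to the GC content of those of replicate 1. The CRE was in 0.712% and 0.147% (0.128% weighted) against 0.447% of shared peaks, and the glucocorticoid and androgen response element in 0.597% and 0.169% (0.164% weighted) against 0.413%. GATA was in 11.1% and 6.39% (9.76% weighted), NR5A in 3.80% and 3.02% (3.55% weighted), and SP and KLF factors in 0.432% and 2.56% (1.19% weighted). Others were closer, with NFY in 2.09% and 1.92%, TEAD in 3.44% and 3.24% and CTCF in 0.883% and 0.818%, the last against 5.69% of shared peaks. Median GC content was 45.3% and 52.0%.

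In paired peaks, promoters exceeded distal sites by a mean log2 height of 1.10 in replicate 1 and 1.71 in replicate 2, a larger contrast in replicate 2 on all 20 chromosomes compared (0.52 to 0.67). Weighting distal pairs to the GC content of promoter pairs left 5.70% of that excess (4.06% to 7.23% over 200 draws of chromosomes), with contrasts of 0.65 and 0.69, so a different GC bias of the libraries is a candidate explanation. Distal pairs alone differed along GC content too, with mean log2 ratios of replicate 2 over replicate 1 from -0.17 in the lowest of 4 GC classes to 0.78 in the highest. Compressed heights in replicate 1 stay open, since weighting by mean height left 49.4% (47.5% to 52.2%). No biological explanation was tested.

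A single copy of the X was tested as the cause of its few peaks by comparing it with autosomes at 2 times the height. The X ratio was then 0.449 and 0.405, below the 0.750 and 0.738 of the lowest autosome, which argues against 1 copy as the whole cause. Fewer genes on the X, with 5.54 against 8.44 per Mb, are argued against as the whole cause. The reason is that 51.7% and 55.8% of X genes had a promoter peak, against 57.5% and 60.4% on the lowest autosome. A single copy can lower these shares too, and both causes together were not tested. Sequence to which reads may not map was not taken out.

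Whether motifs gather near genes of their own pathway was tested by two-sided Fisher's exact tests on shared distal peaks. The NR5A motif was in 4.56% of 461 peaks near cortex genes against 3.38% near other genes (exact test, adjusted p = 0.234), and the CRE in 0.877% of 114 peaks near ACTH and angiotensin genes against 0.482% (0.424). Neither passed after adjustment over 3 tests, and the few peaks near these genes keep the question open.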
